A study of Mus musculus with 6 samples.

How the data were processed

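Total RNA was extracted with Trizol from testes of 8-week-old mice and made into libraries with a directional NEBNext Ultra II kit, per the labels' protocols, and sequenced on a HiSeq2500, per the series' design text. The submitters' processing notes name HISAT2 and the genome build mm10, without versions. The quantifier, the gene annotation and the strand setting are not given in the sources used here. Each sample had 1 deposited table of gene symbols and values. The deposited values were taken as FPKM from the values themselves: they are not whole numbers, their totals differ between libraries, and value times transcript length clusters at whole multiples of a step. In genes with 1 annotated transcript, between 116 and 148 genes per library lay at 1 step and between 17 and 27 at 1.5 steps (within 0.02 on the log10 scale), for a step equal to 1 fragment. That spacing gave 26900000 to 38900000 fragments per library and a floor of 3 fragments on 1 kb of 0.0771 to 0.111 FPKM. Such floors cover counting error only. Normalization by length and depth was done by the authors, and no further scaling was applied in the main comparison.

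The design fixed before the data were examined assumed count tables first and named a log-scale test for FPKM. Since the deposited files hold FPKM, that log-scale test was used, and other fits that need counts were not run. Each table had 25910 rows and 25165 symbols. The values of 333 symbols on 1078 rows were summed per symbol, since the row order differs between tables and copies could not be matched. In all libraries 3943 symbols were listed at 0. Some exact zeros stand beside values of at least 3 FPKM in every other library, so zeros are reported as listed. Symbols were matched to GENCODE M21 and RefSeq positions (GRCm38, the same assembly as mm10): 24975 matched by symbol, 104 by synonym and 86 had no position.

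Libraries were grouped by title because the genotype field contradicts the titles. Nothing in the labels says whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical in part. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes), for 12952 genes with a mean of at least 1 FPKM in one group or more. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes on this scale understate the change of low genes. Of 25 gene lists, 24 had at least 3 tested members; the mitochondrially encoded genes had 0 symbols in these tables. Lists, 22 chromosome sets and 12 symbol families of at least 10 tested genes were tested with camera (preset correlation 0.01), with camera using an estimated correlation, and with fry, which asks whether a set's genes move one way on balance. Sums over families were compared with exact two-sided permutation tests, for which 3 against 3 libraries allow no p under 0.1. Genes were named by a rule written beforehand: the target; 10 fixed genes of the sex chromosomes and Hsf2; the 10 largest changes in each direction among called, non-overlapping genes with descriptive names and the 3 largest among other names; up to 4 members with the smallest p of each called list; and the nearest tested gene on each side of the target.

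Near copies were found with BLAST 2.17.0 (at least 90% identity over at least 50% of the longest transcript), and Y symbols were assigned to families in the same way. Fisher's exact tests used SciPy 1.17.1 and R. The tests were tried on simulated libraries with the means and spreads of these genes, in a fit of 12952 genes. Of 100 genes changed by 0.5 on the log2 scale 71.0% were recovered, and of 100 changed by 1, 95.0%. False calls were 11 of 180, and camera called a planted list and 0 of 20 null lists. The simulated genes varied independently, so the null lists do not test camera on genes that vary together. In the real data the estimated correlation was 0.36 for the round spermatid list and 0.48 for the X-linked multicopy list. Alternatives were other pseudocounts (0.1 and 0.01), other filters, 3 other scalings, other thresholds, no robust estimation, the replicate number as a block, Y genes left out, each library left out, and, added after the data were seen, only symbols on a single row. Figures were drawn with matplotlib 3.10.9.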

Results

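Total RNA from the testes of 8-week-old C57BL/6 mice was sequenced in 6 libraries, 3 titled KO and 3 titled WT. The study removed Teshl, a long non-coding RNA of the testis, and its title concerns multicopy genes of the Y chromosome and the sex ratio of offspring. The titles and the genotype field of the labels contradict each other for all 6 libraries: those titled KO carry the genotype wild type, and those titled WT carry the homozygous loss. The libraries were therefore grouped by title, and each difference below is titled KO minus titled WT. Values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, for 25165 gene symbols. Their sums lay between 393622 FPKM (titled WT replicate 1) and 413604 FPKM (titled KO replicate 2). Spacing of the lowest values put the depth at 26900000 to 38900000 fragments per library. A count of 3 fragments on a 1 kb transcript would then equal 0.0771 to 0.111 FPKM. Correlations of log2 values were 0.991 to 0.993 within the libraries titled KO, 0.989 to 0.992 within those titled WT, and 0.981 to 0.991 between the groups.

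The targeted gene was examined first, since it checks the labels. The non-coding gene 1700027A15Rik, the gene of the RefSeq transcript that the labels name, was nearly absent from the libraries titled KO. Its level was 0.385 FPKM in titled KO replicate 1 and it was listed at 0 in replicates 2 and 3. The libraries titled WT held 1028, 989 and 1081 FPKM. The log2 fold change on the log2(FPKM + 1) scale was -9.86 (SE 0.13, limma adjusted p = 2.91e-08), and all 3 libraries of one group lay apart from all 3 of the other. These values go with the titles and against the genotype field, so the directions below hold for the titles. With a pseudocount of 0.01 the fold change was -14.89 and the limma adjusted p = 0.0644. GENCODE M21 places the gene on chromosome 1, 72984844 to 73025507 of GRCm38, on the plus strand, as an antisense gene. The named transcript has 2 exons, at 73024569 to 73024814 and at 73025322 to 73025507. Tnp1, which encodes transition protein 1 of the condensing spermatid nucleus, lies within the bounds of that gene on the minus strand, at 73015074 to 73015909.

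**Figure D1:**
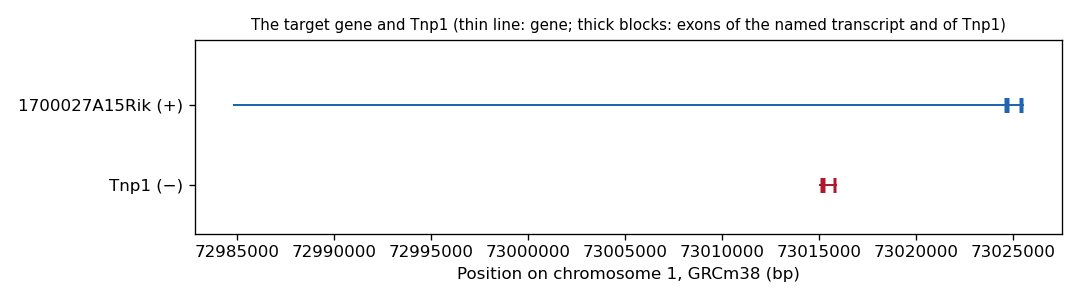
The target gene and Tnp1 on chromosome 1 of GRCm38, with position in bp on the horizontal axis. Thin lines span the genes and thick blocks mark the 2 exons of the transcript named in the labels and the 2 exons of Tnp1, which lies on the opposite strand between 73015074 and 73015909.

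Genes next to the target were compared because a deletion can act on its surroundings. Tnp1 was at 5397 ± 222 FPKM (SD, n = 3) in titled KO and 5110 ± 460 FPKM (SD, n = 3) in titled WT. Its log2 fold change was 0.08 (SE 0.06, limma adjusted p = 0.554), and the libraries of the groups overlapped. On the other side, the nearest tested gene was Tns1, which encodes tensin 1 of focal adhesions, with a log2 fold change of -0.01 (SE 0.05, limma adjusted p = 0.926). It lies 884724 bp away, and the rest of the 5 on that side lie 1210982 to 1262739 bp away. No close gene was therefore tested on that side. None of the 5 nearest tested genes on each side passed the limma threshold, and Igfbp2 alone had an unadjusted p under 0.05 (log2 fold change -0.42, limma adjusted p = 0.234). Without titled KO replicate 3, Igfbp2, which encodes an insulin-like growth factor binding protein, passed (log2 fold change -0.58, limma adjusted p = 0.0426). The exons of the named transcript do not overlap those of Tnp1, and RefSeq positions place Tnp1 137 bp outside the target. The GENCODE bounds of the gene do span Tnp1, and the strand setting of the authors' quantification is not given in the sources used here. Reads of other transcripts of the antisense gene may therefore have been counted to Tnp1. Counting of Tnp1 reads to the target is argued against by the libraries titled KO. There Tnp1 was at 5159 to 5600 FPKM and the target at 0.385 FPKM or listed at 0.

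The 2 groups were then compared over all genes. In the libraries titled KO, 75 of 527 tested X-linked genes were higher, spermatid genes among them, and 12 of 41 tested Y genes were lower. Leaving aside Rab10os and Shoc2, each listed at 0 throughout one group, the largest rises among called genes were in H2al1 genes, which encode short histone H2A variants of spermatids. The largest falls were in the target and in Y genes known by number. Of 12952 tested genes, 102 were higher and 47 lower (limma, Benjamini-Hochberg FDR below 0.05). An absolute log2 fold change of at least 1 was reached by 15 of the higher and 11 of the lower genes. All 149 called genes had no overlap between the 3 libraries of one group and the 3 of the other. Such separation was seen in 21.8% of all tested genes, where chance gives 10%. The median log2 fold change of all tested genes was -0.04. With upper-quartile scaling the split was 121 higher to 33 lower, or 78.6% higher against 68.5% as deposited. Single libraries moved the number of called genes: it was 73 without titled KO replicate 2, 77 without titled KO replicate 3, 81 without titled WT replicate 1 and 233 without titled WT replicate 3.

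The genes with the largest rises among those with descriptive names were mostly X-linked. H2al1b, at 11302432 to 11302926 of the X chromosome, was at 35.8 ± 1.82 FPKM in titled KO and 13.1 ± 1.03 FPKM in titled WT (SD, n = 3 each), 2.73-fold higher (log2 fold change 1.38, SE 0.07, limma adjusted p = 9.42e-06). H2al1g rose 2.57-fold to 142 ± 17.1 FPKM and H2al1k rose 2.21-fold to 69.3 ± 4.27 FPKM. H2al1m was 2.08-fold, H2al1a 2.41-fold and H2al1i 3.21-fold higher. H2al3 rose 2.14-fold, from 57.8 ± 7.59 to 124 ± 6.58 FPKM. Cypt2, a cysteine-rich perinuclear theca gene of spermatids, rose from 60.2 ± 6.15 to 121 ± 8.58 FPKM (2.01-fold, limma adjusted p = 0.000407). Btbd35f4, of a multicopy family, was 2.31-fold higher. Among genes known by number, 1700084M14Rik rose 2.40-fold, 1700003E24Rik rose 2.35-fold to 814 ± 58.3 FPKM, and LOC101055749, which has no position in the annotation used here, rose 2.43-fold. The H2al1 genes are near copies of one another, so how reads were divided among them is uncertain. Leaving out single libraries ended the call of H2al1i in 5 of the 6 cases (titled KO replicates 1, 2 and 3 and titled WT replicates 1 and 2, limma adjusted p = 0.0646 to 0.175). It ended that of H2al1a in 4 (titled KO replicates 1, 2 and 3 and titled WT replicate 1, limma adjusted p = 0.135 to 0.261) and that of Btbd35f4 in 3 (titled KO replicates 2 and 3 and titled WT replicate 2, limma adjusted p = 0.0562 to 0.0762).

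Named genes that were lower lay on several autosomes. Defb33, a beta-defensin gene, fell from 98.9 ± 11.2 to 53.2 ± 6.76 FPKM (SD, n = 3 each; log2 fold change -0.88, SE 0.11, limma adjusted p = 0.0088). Prmt2, which encodes an arginine methyltransferase, fell from 3.30 ± 0.428 to 1.51 ± 0.0216 FPKM. The transcription factor gene Tbx1 fell from 2.76 ± 0.0101 to 1.43 ± 0.294 FPKM, and Tex55, a testis-expressed gene, from 41.2 ± 3.75 to 27.6 ± 0.212 FPKM. Tmed6, Sh2d7, Afap1 and Amd2 were lower with log2 fold changes of -0.66, -0.54, -0.51 and -0.49. Single left-out libraries ended the calls of Amd2 (titled KO replicates 1, 2 and 3 and titled WT replicate 1, limma adjusted p = 0.0737 to 0.148), Sh2d7 (titled KO replicates 2 and 3 and titled WT replicate 1, 0.0792 to 0.0987), Afap1 (titled KO replicate 3 and titled WT replicate 1, 0.0770 to 0.0780), Tmed6 (titled KO replicate 3 and titled WT replicate 2, 0.0504 to 0.0641) and Tbx1 (titled WT replicate 1, 0.0646). Scaling by the median of ratios ended the calls of Afap1 (limma adjusted p = 0.0511) and Amd2 (0.110). The call of Amd2 also ended with upper-quartile scaling (limma adjusted p = 0.0835), without robust estimation (0.0676) and without a filter (0.114), and that of Sh2d7 without a filter (0.0600).

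A pair of named autosomal genes was listed at 0 throughout one group. Rab10os, an antisense gene on chromosome 12, was at 7.53, 6.62 and 7.06 FPKM in titled KO and listed at 0 in all 3 libraries titled WT. Shoc2, which encodes a scaffold of the Ras and MAP kinase pathway, was at 4.51, 5.72 and 4.59 FPKM in titled WT and listed at 0 in all 3 libraries titled KO. Each overlaps another gene in GENCODE M21, Rab10os with Rab10 and Shoc2 with Bbip1. The ribosomal protein genes Rpl30 and Rpl26, which every cell uses, were also listed at 0 in some libraries. Rpl30 was at 0 in titled WT replicate 2 and between 39.2 and 51.6 FPKM in the other libraries. Rpl26 was at 0 in all 3 libraries titled KO and in titled WT replicate 3, and at 54.4 and 49.97 FPKM in the other two, so a zero in these files need not mean absence.

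The distribution of called genes over the chromosomes was compared because the study concerns the sex chromosomes. On the X chromosome, 75 of 527 tested genes were higher and 0 lower by limma (169 higher and 36 lower at an unadjusted p under 0.05), with log2 fold changes of the called genes from 0.35 to 1.63 and a median of 0.62. On the Y chromosome 12 of 41 tested genes were lower and 0 higher by limma (18 lower and 4 higher at an unadjusted p under 0.05). All 12 lay outside the list of short-arm genes. Of 12362 autosomal genes, 26 were higher and 31 lower. The share of higher genes was 14.2% on the X chromosome and 0.210% on autosomes (Fisher's exact test across genes, odds ratio 78.6, 95% CI 49.1 to 130, p = 1.36e-83). For lower genes, Y against autosomes, the odds ratio was 163 (95% CI 69.6 to 369, Fisher's exact p = 4.12e-21). Genes are not replicates, so these intervals describe the genes of these libraries. The odds ratios are for all 6 libraries: autosomal calls were 16 without titled KO replicate 2 and 119 without titled WT replicate 3. The number of X genes called fell to 41 without titled KO replicate 2, to 43 without titled KO replicate 3 and to 37 without titled WT replicate 1.

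**Figure D2:**
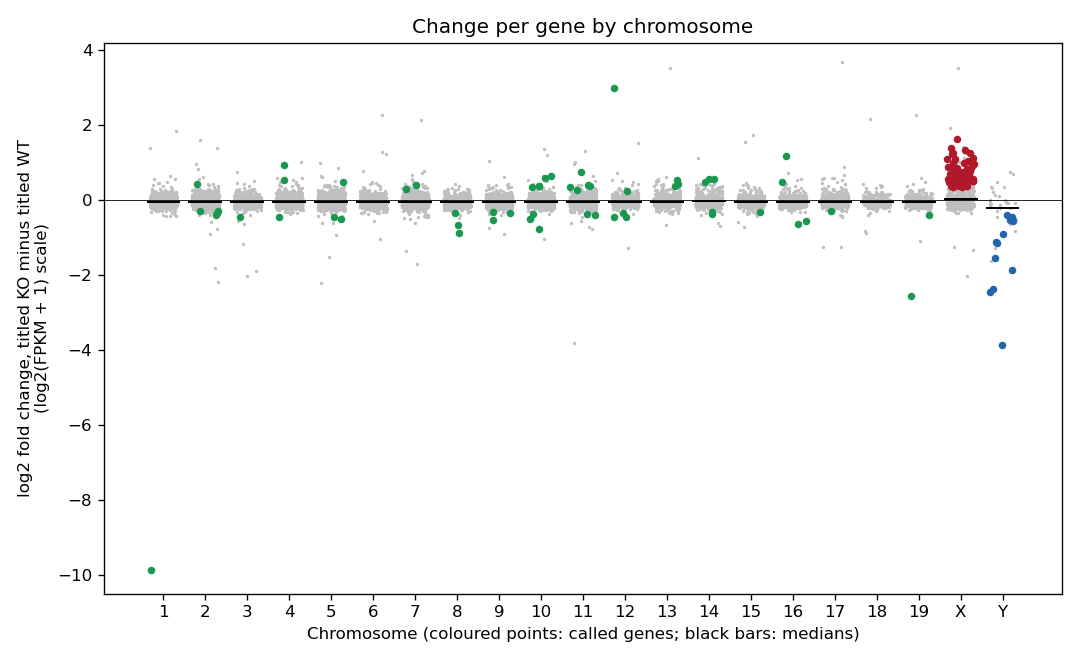
Log2 fold change of each tested gene (titled KO minus titled WT, log2(FPKM + 1) scale, vertical axis) by chromosome (horizontal axis), with called genes coloured and medians as black bars. The target lies at -9.86 on chromosome 1, the coloured points on the X chromosome are 75 genes that all lie above 0, and those on the Y chromosome are 12 genes that all lie below 0.

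As sets, the Y genes outside the short-arm list, the whole Y chromosome and the X chromosome were called by camera, and none of the 19 autosomes was. The Y genes outside the list had a median log2 fold change of -0.44 over 32 tested genes (camera adjusted p = 1.19e-11). The X chromosome had a median of only 0.05 over 527 genes, of which 299 had a positive value (camera adjusted p = 1.2e-16). The median of autosomal genes was -0.044. The X median was -0.00088 without a filter, 0.023 without titled WT replicate 1, 0.075 without titled KO replicate 1 and 0.086 with median-of-ratios scaling. With an estimated correlation none of the 3 sets passed (camera adjusted p = 0.228 for each). By fry, the Y genes outside the list passed (adjusted p = 0.00186) and the X chromosome did not (adjusted p = 0.0903). Adjusted over the list alone, 17 of the 32 Y genes outside the short-arm list were lower and 2 higher, and 143 X genes were higher and 14 lower.

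The multicopy genes of the Y chromosome were then taken one family at a time. Ssty2, a spermiogenesis gene of the long arm that resembles Spin1, fell from 7.14 ± 0.203 FPKM in titled WT to 4.61 ± 0.429 FPKM in titled KO (SD, n = 3 each; log2 fold change -0.54, SE 0.07, limma adjusted p = 0.00721). Sly, a repressor of sex-linked genes in spermatids, was at 0.346 ± 0.0644 FPKM in titled KO and 2.42 ± 1.45 FPKM in titled WT and did not pass (log2 fold change -1.26, limma adjusted p = 0.158). Ssty1 was listed at 0 in all 3 libraries titled KO and at 0.665, 2.93 and 3.35 FPKM in titled WT, and did not pass (limma adjusted p = 0.218). Both passed with a pseudocount of 0.1 (limma adjusted p = 0.0371 for Sly and 0.0121 for Ssty1) and without titled WT replicate 1 (0.00875 and 2.69e-05). Srsy was listed at 0 in 5 of the libraries and at 0.0508 FPKM in titled WT replicate 3, and Rbm31y is not among the symbols analysed here. The list of long-arm multicopy genes, with 4 members tested, had 1 lower and 0 higher by limma (3 and 0 at an unadjusted p under 0.05), and 3 lower adjusted over the list alone. Its median was -0.90 (camera adjusted p = 0.0384, and adjusted p = 0.694 with an estimated correlation; fry adjusted p = 0.0381), and -0.54 without a filter, -1.49 with a pseudocount of 0.1 and -1.63 with a pseudocount of 0.01. Its remaining member Orly had a log2 fold change of 0.22 (limma adjusted p = 0.389). The list was not called by camera without titled KO replicate 1 (adjusted p = 0.0867), without titled KO replicate 3 (0.0828) or with equal library totals (0.0509).

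Most called Y genes carry numbers, and their families were assigned from sequence after their values had been seen. Each Y symbol went to Sly, Ssty1, Ssty2, Srsy or Rbm31y if at least 50% of its longest transcript aligned at 90% identity or more. Called genes fell into the Sly family (3 of 6 tested), the Ssty2 family (6 of 14), the Ssty1 family (1 of 2) and, with the single symbol Gm21379, the Rbm31y family. One more, Gm20826, met none of these limits. Gm20901, of the Sly family, fell from 18.2 ± 1.40 to 2.57 ± 0.579 FPKM (SD, n = 3 each; log2 fold change -2.44, SE 0.11, limma adjusted p = 1.14e-05). Gm21379 was listed at 0 in all 3 libraries titled KO and at 13.7, 11.2 and 15.8 FPKM in titled WT (limma adjusted p = 1.46e-07). Copies share reads, so sums over families are less affected by how reads were divided. The Sly family sum was 16.4 ± 2.06 FPKM in titled KO and 47.2 ± 4.14 FPKM in titled WT, or 34.7%. The Ssty2 family sum was 38.8 ± 2.31 against 61.1 ± 2.06 FPKM, or 63.5%. For the Ssty1 family the libraries titled KO held 0, 0.0985 and 0.0409 FPKM and those titled WT 6.75, 7.40 and 8.26 FPKM. In each of these families every library titled KO lay below every library titled WT (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries allow).

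**Figure D3:**
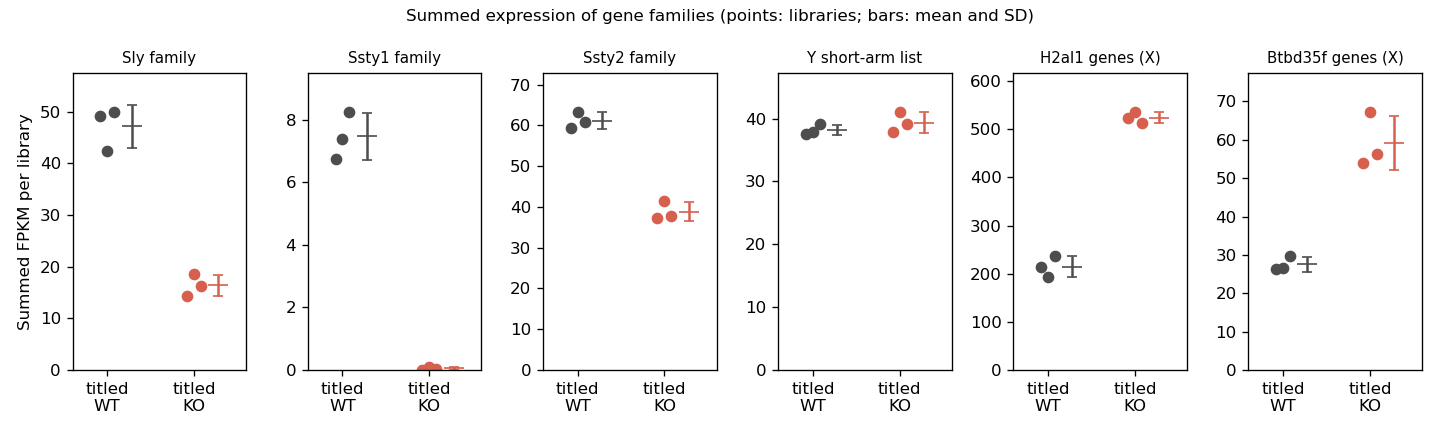
Summed FPKM per library (vertical axes, each from 0) for families of the Y and X chromosomes in titled WT and titled KO, with points for libraries and bars for mean and SD (n = 3). The Sly, Ssty1 and Ssty2 families lie lower in titled KO, the short-arm list overlaps between the groups, and the H2al1 and Btbd35f sums lie higher in titled KO (524 against 214 FPKM for H2al1).

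The Y genes were also summed more widely. Over all 46 Y symbols outside the short-arm list the sum was 156 ± 11.7 FPKM in titled KO and 212 ± 12.7 FPKM in titled WT, or 73.9% (SD, n = 3 each; exact permutation test, two-sided p = 0.1). Its log2 ratio was -0.44, and -1.08 without the symbol with the highest mean, 1700020D14Rik, which had a log2 fold change of 0.36 (limma adjusted p = 0.158). The 22 Y symbols assigned to none of the families, Gm20826 and short-arm genes among them, summed to 141 ± 10.8 FPKM in titled KO and 120 ± 8.09 FPKM in titled WT (SD, n = 3 each; exact permutation test, two-sided p = 0.2). Of the 18 tested among these, Gm20826 alone was called, and it was lower (log2 fold change -1.85, limma adjusted p = 0.000148). The 11 short-arm genes summed to 39.4 ± 1.63 and 38.2 ± 0.849 FPKM (SD, n = 3 each; exact permutation test, two-sided p = 0.5). None of the 9 tested short-arm genes passed limma's threshold over all genes (2 higher and 1 lower at an unadjusted p under 0.05). Adjusted over the list alone, 1 was higher. Their median log2 fold change was 0.01 (camera adjusted p = 0.151). It was -0.0022 with equal library totals and -0.0054 without titled WT replicate 2, but 0.051 with median-of-ratios scaling and 0.068 without titled WT replicate 3. The zinc finger genes Zfy1 and Zfy2 had log2 fold changes of 0.12 (limma adjusted p = 0.470) and 0.33 (0.137).

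Gene lists written before the data were examined placed these changes among the genes of the testis. The X-linked multicopy spermatid list had 6 of 9 tested members higher and 0 lower by limma (8 and 0 at an unadjusted p under 0.05), and 8 higher adjusted over the list alone. Its median log2 fold change was 0.55 (camera adjusted p = 3.9e-13, and adjusted p = 0.537 with an estimated correlation; fry adjusted p = 0.0381). Besides Cypt2, its members with the smallest p were Cypt15 (1.71-fold, log2 fold change 0.73), 1700020N15Rik (1.43-fold, 0.51) and Slxl1 (1.63-fold, 0.69, limma adjusted p = 0.0137), an X-linked relative of Sly. Slx, the other relative, was under 1 FPKM in every library and was not tested. The call of Slxl1 ended without titled WT replicate 1 or 2 (limma adjusted p = 0.0613 to 0.0729), and that of 1700020N15Rik without titled WT replicate 1 (0.0575).

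Lists of autosomal and other spermatid genes shifted by far smaller amounts. Neither the 32 round spermatid genes nor the 31 elongating spermatid genes held a called member by limma (3 and 6 higher and 1 lower in each at an unadjusted p under 0.05), and adjusted over the list alone 0 and 3 were higher. Their medians were 0.07 (camera adjusted p = 0.00717) and 0.04 (camera adjusted p = 0.00209). With an estimated correlation neither passed (adjusted p = 0.851 and 0.758), and fry gave adjusted p = 0.662 and 0.523. The protamine genes Prm1 and Prm2, which package sperm DNA, had log2 fold changes of 0.25 (limma adjusted p = 0.0682) and 0.19 (0.106), and Tnp2, for transition protein 2, 0.35 (0.0735). All 3 passed with equal library totals (limma adjusted p = 0.0202, 0.0395 and 0.0218) and without titled WT replicate 3 (0.0115, 0.0267 and 0.000987), and Prm1 and Tnp2 with upper-quartile scaling (0.0478 and 0.0418). Other members with small p were Izumo1, needed for sperm and egg fusion (0.30), Pgk2, the testis phosphoglycerate kinase (0.18), Akap4 of the sperm fibrous sheath (0.13), Sun5 (0.27) and Rfx2 (-0.12), none of which passed. Single libraries moved the round spermatid median: it was 0.0080 without titled KO replicate 2 and 0.021 without titled WT replicate 2, where camera did not call the list (adjusted p = 0.218 and 0.0768), and 0.12 without titled KO replicate 1 and 0.11 without titled WT replicate 3. The elongating spermatid median was 0.025 without titled KO replicate 2 and 0.026 without titled WT replicate 2. With median-of-ratios scaling the medians were 0.11 and 0.087, and with upper-quartile scaling the elongating median was 0.074.

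Markers of other cells and stages were not called by camera. Median log2 fold changes were -0.10 for spermatogonia, -0.04 for meiotic spermatocyte genes, 0.01 for piRNA pathway genes and 0.02 for the Speer family. Among somatic cells they were -0.08 for Sertoli cells and -0.19 for Leydig cells (camera adjusted p = 0.0901 for both), -0.11 for peritubular myoid cells, -0.21 for fibroblast and matrix genes, -0.01 for macrophages and -0.12 for endothelium. Erythroid, epididymis and adipose lists had medians of -0.04, 0.04 and -0.00. Of these lists 1 member was called, the myosin light chain gene Myl9 (log2 fold change -0.28, limma adjusted p = 0.0475). The Leydig list was called lower with median-of-ratios (camera adjusted p = 0.0241) and upper-quartile scaling (0.0357), without a filter (0.0481), and without titled KO replicate 1 (0.0209), titled WT replicate 1 (0.00576) or titled WT replicate 2 (0.0482). With an estimated correlation and all 6 libraries as deposited, the Leydig and Sertoli lists had camera adjusted p = 0.758 and 0.851, and fry gave adjusted p = 0.276 and 0.523. The Sertoli list was called lower without a filter (0.0219) and without titled WT replicate 1 (0.0152), as was the fibroblast list without titled WT replicate 1 (0.00379), and the macrophage list was called higher without titled WT replicate 2 (0.0076). Heat shock factors and chaperones had a median of -0.06 over 30 tested genes with 0 called by limma (3 lower at an unadjusted p under 0.05; camera adjusted p = 0.467), and Hsf2, a heat shock factor of the testis, a log2 fold change of -0.02 (limma adjusted p = 0.932). Medians were -0.09 for immediate early, -0.08 for interferon response, -0.07 for p53 and apoptosis and -0.07 for cholesterol synthesis genes. The immediate early and cholesterol lists were called lower without titled WT replicate 2 (camera adjusted p = 0.0335 for both). With an estimated correlation and all 6 libraries, their camera adjusted p was 0.894 and 0.851. The testis histone variant list had a median of 0.03 (camera adjusted p = 0.124, and 0.0337 without titled WT replicate 1) and 1 of 14 tested members called, H2al1n (log2 fold change 0.86, limma adjusted p = 0.00254). The direction of camera differed from the sign of the median for the macrophage, erythroid and adipose lists, and the mean of the piRNA list was -0.00. Camera sets a list against the other tested genes, and the median of all tested genes was -0.04. The signs given here are against 0, so a list median near -0.04 does not stand out from all genes. Scaling turned the sign of the median for macrophage, adipose, meiotic and piRNA lists, and single libraries turned others. Without titled WT replicate 2 the median was 0.059 for fibroblast and matrix genes, 0.083 for macrophages, 0.088 for erythroid genes, -0.013 for epididymis and -0.013 for histone variants. Without titled KO replicate 2 it was 0.039 for macrophages, 0.043 for erythroid genes, -0.0036 for piRNA genes, -0.024 for Speer and -0.0057 for histone variants. Without titled KO replicate 3 it was 0.14 for erythroid, -0.035 for piRNA and 0.0079 for adipose genes, and without titled WT replicate 1 it was -0.014 for piRNA, -0.045 for Speer and 0.036 for adipose genes. The adipose median was 0.036 without titled KO replicate 1 and 0.033 without titled WT replicate 3. Other medians kept their sign without single libraries but varied: -0.12 to -0.042 for spermatogonia, -0.064 to -0.022 for meiotic, -0.18 to -0.0093 for peritubular myoid, -0.20 to -0.075 for endothelial, -0.098 to -0.029 for heat shock, -0.16 to -0.047 for immediate early, -0.12 to -0.041 for interferon, -0.11 to -0.037 for p53 and -0.10 to -0.015 for cholesterol genes. Titled WT replicates 1 and 2 set the extremes for the meiotic, myoid, heat shock and p53 lists. The erythroid median was -0.32 without titled KO replicate 1, and the epididymis median 0.11 without titled WT replicate 3. The Speer median was 0.12 without titled KO replicate 1 and the macrophage median -0.12 without titled WT replicate 3. Without titled WT replicate 1 the fibroblast median was -0.34 and the Sertoli median -0.12.

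Families formed from symbols alone were compared as well. The H2 and Hist family had 10 of 61 tested genes higher and 0 lower by limma (17 higher and 5 lower at an unadjusted p under 0.05; Fisher's exact test for called genes, adjusted p = 9.82e-09). These were 8 H2al1 genes, H2al3 and H2ap, all X-linked. Its median was 0.02 (camera adjusted p = 1.28e-07, and adjusted p = 0.323 with an estimated correlation), between 0.0053 with equal library totals and 0.072 with median-of-ratios scaling, and 0.030 to 0.044 without any one of the libraries other than titled WT replicate 1. The Tex family had 3 higher and 1 lower of 36 (Fisher's exact adjusted p = 0.00298; camera adjusted p = 0.00528, and adjusted p = 0.469 with an estimated correlation), and the 3 higher were the X-linked Tex13a, Tex13c1 and Tex13c3. The Tex call ended without titled WT replicate 2 (camera adjusted p = 0.0765) and the Catsper call without titled KO replicate 2 (0.0589). Genes named Gm with a number had 24 higher and 12 lower of 419, and genes named Rik 19 higher and 1 lower of 902. Most of the higher Gm genes are X-linked and most of the lower ones Y-linked, so they largely repeat the calls on those chromosomes. The higher Rik genes are X-linked in part, and the lower one is the target. The Adam, Spata, Catsper and Olfr families were called up and the ribosomal Rpl and Rps family down by camera, each with 0 called genes by limma (at an unadjusted p under 0.05, 5 Adam, 3 Spata, 1 Catsper and 3 Olfr genes were higher, 1 Spata and 1 Olfr gene lower and 15 ribosomal genes lower). The Gm and Rik families were called up too, and none of the 12 tested families passed with an estimated correlation (adjusted p of at least 0.323).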

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

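The setting that kept only symbols on a single row, the families assigned by sequence and the H2al1 and Btbd35f sums were chosen after the data were seen; the other settings were planned. Planned fits that need counts were not run, since the files hold FPKM. The numbers of called genes depended on the setting more than directions did: no called gene that was tested changed sign under any setting. The X chromosome had 1 gene called lower with a pseudocount of 0.01, with equal library totals and without titled WT replicate 1 or 3, and Y had 2 called higher without titled KO replicate 1. Without a filter 88 genes were called (56 higher), 44 of them higher on X, and 23 autosomal genes were called. Scaling by the median of ratios gave 28 lower genes and 37 autosomal calls, and no robust estimation gave 35 autosomal calls. Leaving out the Y genes gave 31 lower genes and 1 called chromosome set. With symbols on a single row there were 27 lower genes, 0 lower Y genes and 1 called chromosome set, and the camera direction turned for the Y genes outside the short-arm list (median -0.066) and for the whole Y chromosome (-0.010); that setting removes most multicopy Y genes. At FDR below 0.01, 57 genes were called (38 higher, 19 lower), with 31 on X and 12 autosomal. With an absolute log2 fold change of at least 1 there were 26 (15 higher, 11 lower), with 12 on X, 7 on Y and 4 autosomal. With a pseudocount of 0.01 the target had a log2 fold change of -14.89 (limma adjusted p = 0.0644). With an estimated correlation camera called 0 lists, 0 chromosome sets and 0 families, and fry called 2 lists. The summed Y signal without the symbol with the highest mean had a log2 ratio of -1.08.

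Replicate numbers did not pair the libraries: correlations of same-numbered deviations were 0.0647, -0.129 and 0.0614. With the number as a block, 50 genes were called (32 higher, 18 lower), 26 of them higher on X and 9 autosomal. The block cannot change a fold change in this balanced design, -9.86 for the target included, only its error. It ended the calls of 1700020N15Rik and H2al1a (limma adjusted p = 0.0693 for both), Cypt15, Slxl1 and Tbx1 (0.0502 for each), Tmed6 (0.0540), Sh2d7 (0.0639), Afap1 (0.0898), Defb33 (0.0952) and Amd2 (0.145), and camera called the Leydig list lower (adjusted p = 0.0448). The call of H2al1a also ended with the Y genes left out (limma adjusted p = 0.0511). Leaving out 1 library gave 73 to 233 called genes (49 to 184 higher, 23 to 49 lower), 37 to 94 on X, 16 to 119 autosomal, 3 to 8 called lists and 0 to 1 called neighbours. Hsf2, with a log2 fold change of -0.02, turned to 0.023 and 0.011 under median-of-ratios and upper-quartile scaling and lay between -0.111 and 0.031 over single left-out libraries. Tns1 (-0.01) turned to 0.031 and 0.019 under those scalings and lay between -0.033 and 0.0086 over single left-out libraries. The cause of these changes was not tested, apart from fewer genes or libraries entering a fit. Depth limits low genes: 3 fragments on 1 kb equal up to 0.111 FPKM.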

Other observations

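The tests in this part were chosen after the results were seen, except that the other scalings were planned. Further X-linked families were counted, without a test of each family as a set. Of 12 tested Btbd35f genes 5 were called and all had positive values, with a median log2 fold change of 0.89, and the summed family was 59.2 ± 7.16 FPKM in titled KO and 27.5 ± 1.91 FPKM in titled WT (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest possible). The H2al1 sum was 524 ± 11.6 against 214 ± 21.4 FPKM, with log2 ratios of 1.22 to 1.37 over all scalings and left-out libraries. Of the Tex13 genes 3 of 4 were called, of the Cypt genes 3 of 5, of the Samt genes 1 of 6 and of the Mageb genes 1 of 5. The 8 tested Rhox genes, a reproductive homeobox cluster that includes Rhox5 and Rhox8 of the Sertoli list and Rhox13 of the spermatogonia list, had a median of 0.25 and 0 called by limma (4 higher and 0 lower at an unadjusted p under 0.05). X genes with near copies were called higher more often (43 of 145, 29.7%) than X genes without (32 of 379; Fisher's exact p = 6.02e-09, across genes). That test takes genes as independent, but near copies share reads, so its p may be too small. The 43 include 8 H2al1 and 5 Btbd35f genes. Single-copy X genes that rose include Tspan6 (log2 fold change 0.57), Cylc1, which encodes cylicin 1 of the sperm head (0.52), Actrt1 (0.61), Cdk16 (0.38) and H2ap (0.63).

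Of 22 tested symbols without a position, 4 were lower and 1 was higher. The 16 symbols that begin with LOC115489, which have no position in the annotation used here, summed to 3.30 ± 0.293 FPKM in titled KO and 18.6 ± 0.217 FPKM in titled WT (SD, n = 3 each), or 17.8%. Among autosomal genes outside the naming rule, Ybx1, which encodes a Y-box RNA-binding protein, was singled out after its values were seen. It rose from 216 ± 12.8 to 413 ± 33.6 FPKM (SD, n = 3 each; log2 fold change 0.93, limma adjusted p = 0.00015). Ybx1 has 3 near copies by sequence, covering up to 59.5% of its transcript, so how reads were divided among them is uncertain.

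The rise of the 75 called X-linked genes in titled KO was not accounted for in full by the technical explanations tested, and a biological difference is a hypothesis. If reads shared between copies made it, single-copy X genes would not stand out. Of them 8.44% were called higher, against 0.210% of autosomal genes (Fisher's exact p = 4.21e-34, across genes). The median log2 fold change of all 379 single-copy X genes was -0.0014, however, against -0.044 for autosomal genes. As the whole cause, a larger share of spermatids would lift spermatid genes at large as much. The X-linked multicopy list had a median of 0.55 against 0.07 and 0.04 for the round and elongating spermatid lists. Of 527 tested X genes 75 were called higher, against 0 of 62 autosomal genes of those spermatid lists (Fisher's exact p = 0.00019, across genes). Only 26 of 12362 autosomal genes were called higher, so that p largely repeats the contrast of X with autosomes. Each of the 3 other scalings gave at least 61 X genes called higher. A somewhat larger share of spermatids stays possible as a part, but the values do not settle it. At the preset correlation camera called up both spermatid lists and the Spata, Catsper and Adam families, which share members with those lists. None of these passed with an estimated correlation (camera adjusted p of at least 0.44) or by fry (adjusted p of at least 0.523). The Tex family was also called up, but its 3 higher genes are X-linked. The Leydig, Sertoli and fibroblast medians were -0.19, -0.08 and -0.21, and the fibroblast median was 0.059 without titled WT replicate 2. The lower Sly signal, the genotype or a shift of stage among spermatids was not tested.

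If reads moved among Y symbols of similar length, the FPKM sum of a family would not change. The sums argue against that as the cause of the fall of Y multicopy genes. Copy lengths were not compared, and reads moving to a longer copy would lower a sum, so such moves were not excluded. The Ssty2 family sum stood at 63.5%, and the Sly and Ssty1 sums were also lower in every library titled KO. The Ssty2 sum holds 20 symbols, while 284 other annotated genes match Ssty2 by sequence. Reads moving to copies outside the sums were therefore not excluded. As the whole cause, fewer spermatids would lower spermatid genes at large. The Y genes outside the short-arm list had a median of -0.44, against 0.07 and 0.04 for the round and elongating spermatid lists. Of these 32 tested Y genes 12 were called lower, against 0 of the 62 autosomal spermatid genes (Fisher's exact p = 4.73e-07, across genes). Only 31 of 12362 autosomal genes were called lower, so that p largely repeats the contrast of Y with autosomes. Camera called the round and elongating spermatid lists up at the preset correlation, but not with an estimated correlation (camera adjusted p = 0.851 and 0.758). Loss or variation of part of the long-arm DNA in the animals titled KO cannot be told apart from silencing of the copies, because both would leave no RNA. The Ssty1 family reached at most 0.0985 FPKM in those libraries, in titled KO replicate 2, where 3 fragments on a single 1 kb transcript equal 0.0927 FPKM. That floor is a rough guide only, since the sum covers 3 symbols whose lengths may differ from 1 kb. Gm21379 was listed at 0 in each library titled KO, but a listed zero need not mean absence in these files. RNA values alone leave loss and silencing open, and a DNA copy number test of these families would separate them.

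The zeros of Rab10os and Shoc2 may come from failed estimates at single genes. Of 62 symbols listed at 0 in some libraries and at 3 FPKM or more in every other, 59 had zeros that did not follow the groups, Rpl30 among them. Some of the 62 are microRNA or small nucleolar RNA genes. Only the 11 with zeros in exactly 3 libraries could follow the groups, so the rest do not bear on that question. Of these 11, 8 cut across the groups, Adat2 and Cdc23 among them, and 3 followed them, namely Gm21379, Rab10os and Shoc2. Rab10, which overlaps Rab10os, reached at most 15.04 FPKM in titled KO and 16.8 to 18.3 FPKM in titled WT, while Bbip1, which overlaps Shoc2, was at 19.9 to 26.4 FPKM in titled KO and 16.7 to 22.4 FPKM in titled WT. A true difference in either gene stays possible and was not tested.

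The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split called 149 genes, the highest of the others called 4, and 1 split, the real one, reached the real number.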
